A study of Mus musculus with 4 samples.

How the data were processed

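Total RNA from the skin of E16.5 mouse embryos (E, embryonic day) was hybridised to 4 Affymetrix whole-transcript arrays, 2 for control embryos and 2 for embryos that overexpress the transcription factor Ovol2 in the epidermis (Ovol2 BT). Per the labels' protocols, each array received RNA of 2 mice, Ovol2 BT embryos carried both a tetracycline-responsive Ovol2 transgene and a transactivator driven by the keratin 5 promoter, and controls carried the Ovol2 transgene alone or were wild type. No control with the transactivator alone was among the samples analysed here. Per the labels' protocols, RNA was extracted with Trizol and columns, and the targets were prepared with random primers.

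The deposited values are intensity values on a linear scale, 1 per probe set and array, which the authors made with Affymetrix Expression Console 1.1.1 and the PLIER 2.0 summary, per the submitters' processing notes. The step that normalised the arrays against each other and the genome build behind the probe sets are not given in the sources used here. The table held 35557 probe sets and 0 columns of other samples. The platform annotation gave 1 gene symbol for 21789 probe sets, several for 1621 and no listed gene for 12147; these last 2 kinds stayed out of the gene test and were named by no gene. Symbols were updated through the Entrez number to the RefSeq table of GRCm38.p6, which matched 21698 of the probe sets with 1 symbol; the other 91 kept the annotation's symbol. No coordinates are printed because the build of the probe sets is unknown. Arrays give no read depth, and their number limits the precision. Median signals were 282, 299.5, 304 and 266 for control replicates 1 and 2 and Ovol2 BT replicates 1 and 2.

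Values were taken to log2(intensity + 16), an offset that shrinks the folds of dim genes, with no further normalisation. Of the probe sets of a gene the one with the highest mean over the 4 arrays was used, which mattered for 999 genes. Of 19938 genes, those with a mean under the 25th percentile (log2 level 7.32) were left out, and 14953 were tested. limma 3.58.1 in R 4.3.3 (with statmod 1.5.0) fitted Ovol2 BT minus control over the 4 arrays with lmFit and eBayes with an intensity trend, a two-sided moderated test with 2 residual and 3.45 prior degrees of freedom, and Benjamini-Hochberg adjustment over all genes tested. A gene was called changed at an adjusted p under 0.05. An exact permutation test of 2 arrays against 2 cannot go below p = 0.333, so none was used.

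The design, 39 gene lists with 833 genes and the rule for named genes were fixed before the data were examined. The lists cover epidermal layers, periderm, hair follicle, signalling pathways, cell cycle, stress and other cell types of embryonic skin; 4 of them are checks (the Ovol family, sex genes, the major histocompatibility complex and other strain-variable genes). Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 39 lists, and list members were also adjusted over the list alone. With an estimated correlation instead, camera had only the 2 residual degrees of freedom. The smallest unadjusted camera p was then 0.0232 (periderm), and no list passed over the 39. Lists of negative estimated correlation, such as melanocyte (-0.081), lost their calls too, at the same adjusted p of 0.435. Others had estimates above the preset, such as keratinocyte stress (0.187), myeloid (0.112), basal keratinocyte (0.096), cornified envelope (0.080) and periderm (0.070). For these the p at the preset correlation may be too small. Loss of a call with the estimated correlation thus cannot tell correlated genes from too few arrays, and the calls rest on the preset correlation. The rule named 12 genes in advance, all genes past the threshold up to 12 per direction, up to 4 changed members of each list described or the 2 with the largest fold where none changed, and the sex genes. List members that passed only over the list alone, genes at an adjusted p under 0.1 and those in the closing section were chosen after their values were seen.

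The steps were tested on simulated data with 14953 genes and 200 of them changed, in 10 runs. At a log2 fold of 1 the fit recovered 9.6% of the changed genes, at 2 it recovered 83%, at 3 it recovered 95.6% and at 4 it recovered 99.2%, with 9.4 false calls a run. A simulated list of 15 genes shifted by 0.7 had an unadjusted camera p under 0.05 in 10 of 10 runs at either correlation. This count left out the adjustment over all lists that the calls on the data needed. It thus does not give the power of the estimated correlation for those calls, and their loss there cannot be held against a list. Simulated genes varied independently of each other, so the runs cannot tell whether the preset correlation is right for the data.

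Alternatives fixed in advance were quantile normalisation, median centring, offsets of 1 and 64, no filter and a filter at the 50th percentile, the mean of a gene's probe sets, a variance without trend, a robust variance, the replicate number as a block, leaving out each array in turn, an adjusted p under 0.1, a minimum of 2-fold, leaving out strain-variable genes, all probe sets, an estimated correlation, and fry. Array weights, cyclic loess, removal of a trend with gene length, and a crossed pairing were added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.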

Results

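Gene expression was measured in skin of E16.5 mouse embryos, an age at which, in the submitters' description, skin of the 2 genotypes still looked much alike. There were 2 control arrays and 2 Ovol2 BT arrays, each of RNA from 2 mice, and the values are deposited PLIER intensities on the log2(intensity + 16) scale. Ovol2 is a zinc finger transcription factor of epithelia, and the comparison asks which transcripts differ early when it is overexpressed in basal keratinocytes.

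Ovol2 itself rose in Ovol2 BT skin, by 5.01 on the log2 scale (SE 0.27, limma adjusted p = 0.0253, n = 2 arrays per group). Its level was 7.59 and 8.29 on the control arrays and 12.93 and 12.96 on the Ovol2 BT arrays, so the labels match the Ovol2 level on every array. Whether the probes read the transgene, the endogenous transcript or both was not examined. Ovol1, its close relative, differed by 0.06 (SE 0.18, adjusted p = 0.959).

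Of 14953 genes tested with limma, 4 changed, 3 of them higher and 1 lower, each with an adjusted p of 0.0253. Besides Ovol2, the keratins Krt6b and Krt8 rose. Krt6b, a keratin of stressed or wounded epidermis, rose by 4.30 (SE 0.25), from 8.22 and 7.73 to 12.42 and 12.12. Krt8, a keratin of simple epithelia and periderm, rose by 2.34 (SE 0.12), from a mean of 10.95 (SD 0.07) to 13.29 (SD 0.13). Akr1d1, a steroid reductase, fell by 2.17 (SE 0.13), from 8.55 and 8.59 to 6.40 and 6.39, under the level of 7.32 that served as the filter on dim genes. At an adjusted p under 0.1, 4 more genes stood out after their values were seen. They were Krt5 (-0.87, SE 0.06, adjusted p = 0.0597), the tight junction gene Cldn6 (2.63, SE 0.22, adjusted p = 0.0945), the iodide transporter Slc5a5 (1.74, SE 0.15, adjusted p = 0.0945) and the stress keratin Krt16 (3.38, SE 0.29, adjusted p = 0.0945). An unadjusted p under 0.05 was found for 632 genes (372 higher, 260 lower), against 748 expected by chance. The groups did not overlap for 34.2% of genes, against 33.3% by chance. All 4 calls were lost in limma with a variance without trend, where 0 genes passed and 601 had an unadjusted p under 0.05, and with cyclic loess, where 0 passed and 673 had one; a test of all probe sets, without collapsing to genes, also called 0. Akr1d1 also missed the threshold once a trend with gene length was removed (-2.09, adjusted p = 0.0503). The count was 110 without Ovol2 BT replicate 2, 2432 without Ovol2 BT replicate 1, 11 without control replicate 1 and 9 with the replicate number as a block, which added Krt5, Krt16, Cldn6, Il1a and Lipn.

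**Figure D1:**
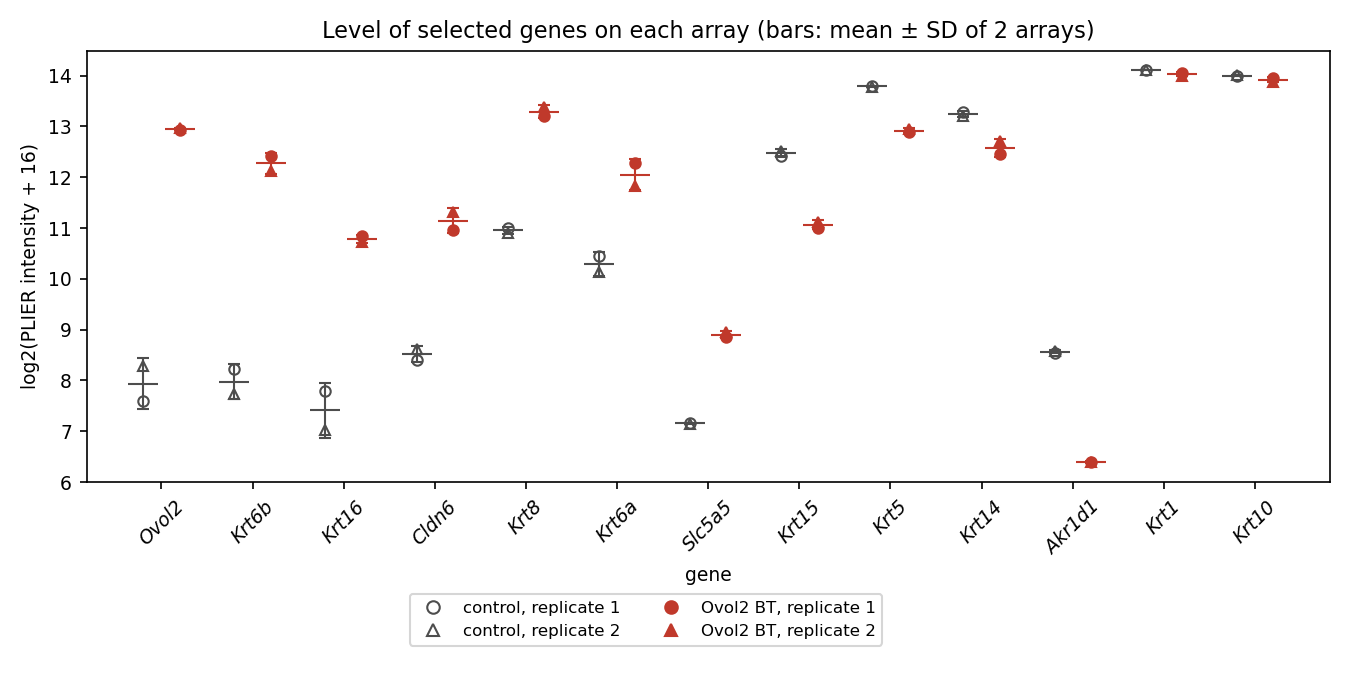
Log2(PLIER intensity + 16) of 13 genes on each of the 4 arrays, with the mean and SD of the 2 arrays of each group; open symbols are control, filled symbols Ovol2 BT. Ovol2, Krt6b and Krt8 lie higher and Akr1d1 lower on both Ovol2 BT arrays, while Krt1 and Krt10 differ by -0.08 each.

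Genes typical of periderm, the outermost transient layer of the fetal epidermis, were higher in Ovol2 BT skin. The list shifted up, with a median log2 fold of 0.74 over 15 genes (camera adjusted p = 8.56e-16; adjusted p = 0.435 with an estimated correlation). Of its members 1, Krt8, rose over all genes tested, and 11 were higher when adjusted over the list alone. Cldn6 (2.63), Krt6a (1.76), Krt18 (1.20) and the GABA receptor subunit Gabrp (0.90) were among these. The list's median was 0.71 on each Ovol2 BT array against the control mean.

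Some genes of the granular layer and cornified envelope, which build the skin barrier, were also higher. The list shifted up, with a median of 0.27 over 40 genes (camera adjusted p = 5.39e-12; adjusted p = 0.435 with an estimated correlation). None of its 40 members passed over all genes tested in limma, with 22 at an unadjusted p under 0.05 (20 higher, 2 lower), and 18 were higher when adjusted over the list alone. Higher examples were the cornified envelope genes Sprr2d (1.63), Lce1b (1.21) and Lce1i (1.20) and the transglutaminase Tgm5 (0.96). In all, 30 members had positive and 10 negative folds. The 2 lower members at an unadjusted p under 0.05 were the transglutaminase Tgm3 (-1.22) and Scel (-0.69). Tgm1 (-0.06) hardly differed, so the rise did not extend to the whole list. Lor differed by 0.02, but it was bright (13.92 and 13.88 on the control arrays). Whether the arrays limit the folds of bright genes was not examined. Flg2 (1.35, SE 0.50) did not pass over the list alone (adjusted p = 0.0762), and its value was 0.58 without control replicate 2. Keratinocyte stress genes shifted up as well, with a median of 0.28 over 17 genes (camera adjusted p = 1.08e-07; adjusted p = 0.435 with an estimated correlation). In this list Krt6b rose over all genes tested, and 8 genes were higher and 1 lower when adjusted over the list alone, including Krt16 (3.38), the cytokine Il1a (2.42) and Krt6a (1.76). Without Ovol2 BT replicate 1 the camera adjusted p of the stress list was 0.0911. The lists share members such as Krt6a, Krt17 and Sprr2d, and Krt6a and Krt6b or the Lce1 genes are near-identical copies whose probes were not examined for cross-hybridisation.

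The keratins of the basal layer were lower, and the basal keratinocyte list leaned the same way. The list shifted down, with a median of -0.21 over 17 genes (camera adjusted p = 8.37e-05, and 0.435 with an estimated correlation). Its median difference between the 2 control arrays (replicate 2 minus replicate 1) was 0.25, as large as that between genotypes. No member passed over all genes tested, and 3 were lower when adjusted over the list alone, namely Krt15 (-1.41, SE 0.13), Krt5 (-0.87) and Krt14 (-0.66, SE 0.11). The basal regulator Trp63 differed by -0.21 (SE 0.18), by -0.36 without Ovol2 BT replicate 1 and by -0.07 without Ovol2 BT replicate 2. Spinous differentiation genes shifted down, with a median of -0.09 over 15 genes (camera adjusted p = 0.00409; adjusted p = 0.435 with an estimated correlation), with Dsg1b at -0.63, which was -0.11 without Ovol2 BT replicate 2, and Lgals7 at -0.33, which was -0.15 without Ovol2 BT replicate 1. The spinous keratins Krt1 (-0.08, SE 0.04) and Krt10 (-0.08, SE 0.05) did not pass. Without Ovol2 BT replicate 1 the camera adjusted p was 0.0661 for the basal and 0.119 for the spinous list, and the spinous call was also lost with median centring (0.111) and a variance without trend (0.132).

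Among hair follicle and signalling lists, the hedgehog response and dermal condensate lists shifted down. No member of either passed over all genes or over the list alone. The hedgehog list had a median of -0.36 over 8 genes (camera adjusted p = 0.0151; adjusted p = 0.435 with an estimated correlation), with the inhibitor Hhip at -0.68 and the effector Gli1 at -0.55 (-0.33 without Ovol2 BT replicate 1). The dermal condensate list, of the cell cluster under the hair placode, had a median of -0.20 over 20 genes (camera adjusted p = 0.0469; adjusted p = 0.435 with an estimated correlation), with Inhba at -0.82 and Trps1 at -0.80. Without Ovol2 BT replicate 2 these were -0.02 and -0.38. A dimmer Trps1 probe set gave -1.55. The hedgehog adjusted p was 0.303 without Ovol2 BT replicate 1, 0.0611 without control replicate 1 and 0.358 with the filter at the 50th percentile; that of the condensate list was 0.055 with the replicate block, 0.212 without Ovol2 BT replicate 1, 0.0684 without Ovol2 BT replicate 2 and 0.136 without control replicate 1, and it lay between 0.0543 and 0.639 with quantile normalisation, the 50th percentile filter, array weights, cyclic loess and the length trend removed. Hair placode and follicle epithelium genes went both ways (median 0.08 over 36 genes, camera adjusted p = 0.273). When adjusted over that list alone, 4 were higher and 1 lower, among them Padi3 (1.23), Bmp2 (0.93), Sostdc1 (0.72) and, lower, the placode regulator Lhx2 (-1.03). Wnt response (median 0.06, adjusted p = 0.838) and Notch pathway genes (0.05, adjusted p = 0.290) did not pass, with Dkk1 at -0.71, Lef1 at -0.57 (SE 0.21), Dtx1 at 0.37 and Mfng at 0.21. Without Ovol2 BT replicate 2, Lef1 was -0.81 (adjusted p = 0.0414) and Mfng -0.04, and without Ovol2 BT replicate 1 they were -0.33 and 0.45. Retinoid pathway genes had a median of 0.00 (0.00405, adjusted p = 0.787).

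Lists of epithelial and mesenchymal state did not pass as groups in the main fit. Epithelial adhesion and polarity genes had a median of -0.07 over 44 genes (camera adjusted p = 0.106), and passed without control replicate 1 (mean -0.06, adjusted p = 0.0308); Cldn6 (2.63) and Cldn8 (-1.67), both claudins of tight junctions, passed over the list alone. Cdh1, the epithelial cadherin, differed by 0.07 (SE 0.11) and Ctnna1 by 0.05 (SE 0.15). Mesenchymal transition genes had a median of 0.07 over 28 genes (adjusted p = 0.273), with Tgfbr1 at -0.89 and Tgfb1 at 0.38, which without Ovol2 BT replicate 2 were 0.01 (0.0118) and 0.21, Zeb1 at -0.10 (SE 0.22) and Vim at -0.01 (SE 0.06). None of these named genes changed in limma. Vim was bright (control mean 13.77), and a limit on the folds of bright genes was not examined. Barrier lipid genes did not pass either (median -0.10 over 25 genes, mean -0.03, adjusted p = 0.181), with Lipn at 1.98 and Sptlc3 at -0.87.

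The mitosis list shifted down, with a median of -0.11 over 28 genes (camera adjusted p = 0.0321, and 0.435 with an estimated correlation). Against the control mean its median was -0.08 on Ovol2 BT replicate 1 but 0.00 (0.00193) on replicate 2. No member had an unadjusted p under 0.05 in limma. None passed over all genes or over the list alone, and the kinetochore genes Cenpe (-1.10) and Bub1 (-1.01) rested on Ovol2 BT replicate 2, without which they were -0.43 and -0.11. The list's adjusted p was 0.0772 without Ovol2 BT replicate 2, 0.0917 without Ovol2 BT replicate 1, 0.143 with the filter at the 50th percentile and 0.0565 with cyclic loess. S phase and DNA replication genes had a median of 0.04 (adjusted p = 0.838). Other stress and metabolic lists did not pass in the main fit: p53 response (-0.03, adjusted p = 0.271), heat shock and unfolded protein (-0.12, adjusted p = 0.269), immediate early (0.05, adjusted p = 0.271), hypoxia and glycolysis (-0.06, adjusted p = 0.397) and cholesterol synthesis (0.11, adjusted p = 0.290). Without control replicate 1, S phase (mean 0.19, adjusted p = 0.0247), cholesterol synthesis (0.18, adjusted p = 0.0350) and hypoxia genes (-0.29, adjusted p = 0.000143) passed, the last in the other direction without control replicate 2 (0.17, adjusted p = 0.0210). Heat shock genes passed with the length trend removed (-0.19, adjusted p = 0.0146).

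Among markers of other cell types, the macrophage and myeloid list shifted up and the melanocyte list down. The myeloid list had a median of 0.38 over 22 genes (camera adjusted p = 0.000132; adjusted p = 0.435 with an estimated correlation), with the lysozymes Lyz1 at 0.67 and Lyz2 at 0.63. The melanocyte list had a median of -0.23 over 12 genes (camera adjusted p = 0.0149; adjusted p = 0.435 with an estimated correlation), with the pigment enzyme Tyr at -0.82 and Mitf at -0.45, which were -0.47 and -0.06 without Ovol2 BT replicate 2. Interferon response genes were higher (median 0.23 over 12 genes, camera adjusted p = 0.0234; adjusted p = 0.530 with an estimated correlation), with Oasl2 at 0.71 but Ifit2 at -0.63, which was -0.06 without Ovol2 BT replicate 2. No member of the myeloid, melanocyte or interferon list passed over all genes or over the list alone. Between the control arrays (replicate 2 minus replicate 1) the myeloid median differed by -0.19. The interferon call was lost once the trend with gene length was removed (camera adjusted p = 0.180). Without Ovol2 BT replicate 1 the adjusted p was 0.0661 for the myeloid, 0.119 for the melanocyte and 0.407 for the interferon list; it was 0.0807 for the melanocyte list without control replicate 2 and 0.0904 with the filter at the 50th percentile, and for the interferon list 0.0973 without control replicate 1. Markers of endothelium (median 0.14, adjusted p = 0.0717), dermal fibroblasts (0.05, adjusted p = 0.273), pericytes and smooth muscle (0.09, adjusted p = 0.287), Schwann cells and nerve (0.14, adjusted p = 0.269), adipocytes (0.15, adjusted p = 0.273), mast cells (0.13, adjusted p = 0.273), lymphocytes and Langerhans cells (0.14, adjusted p = 0.266), and cartilage and bone (0.11, adjusted p = 0.292) did not pass in the main fit. Merkel cell markers had a median of -0.06 but a mean of 0.39, led by Krt8 (adjusted p = 0.199). They passed with the filter at the 50th percentile (adjusted p = 0.000238) and without control replicate 1 (mean 0.42, adjusted p = 0.0247), as did adipocyte genes without control replicate 1 (0.36, adjusted p = 0.0247). Lymphocyte and Langerhans genes passed without control replicate 2 (0.40, adjusted p = 0.00203), and endothelial genes without control replicate 2 (0.17, adjusted p = 0.0476) and with cyclic loess (0.12, adjusted p = 0.0464).

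Blood and muscle markers differed between arrays of one genotype. Erythroid genes had a median of -0.27 on Ovol2 BT replicate 1 and 1.21 on replicate 2 against the control mean (list median 0.40, camera adjusted p = 0.152), with Alas2 at 0.66 and Tspo2 at 1.78, which read 6.90 and 7.30 on the control and 7.13 and 10.64 on the Ovol2 BT arrays and was 3.54 without Ovol2 BT replicate 1. Skeletal muscle genes had medians of -0.37 and 0.56 on these arrays (list median 0.08, adjusted p = 0.434), with Myh7 at 0.39 and Tnni2 at 0.34. With the replicate number as a block, which follows the Y-linked signal described with the sex genes, the erythroid list passed (mean log2 fold 0.48, adjusted p = 0.00074). It also passed without control replicate 2 (0.88, adjusted p = 9.38e-08) and without Ovol2 BT replicate 1 (1.24, adjusted p = 8.91e-05), and the skeletal muscle list passed without control replicate 1 (0.48, adjusted p = 2.16e-11) and without Ovol2 BT replicate 1 (0.54, adjusted p = 8.91e-05). Both passed in the other direction without Ovol2 BT replicate 2 (-0.32, adjusted p = 0.0397, and -0.35, adjusted p = 6.34e-06), as did the skeletal muscle list without control replicate 2 (-0.29, adjusted p = 3.73e-06). Without Ovol2 BT replicate 2, Alas2 was -0.21, Tnni2 -0.32 and Myh7 0.00 (0.00238).

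**Figure D2:**
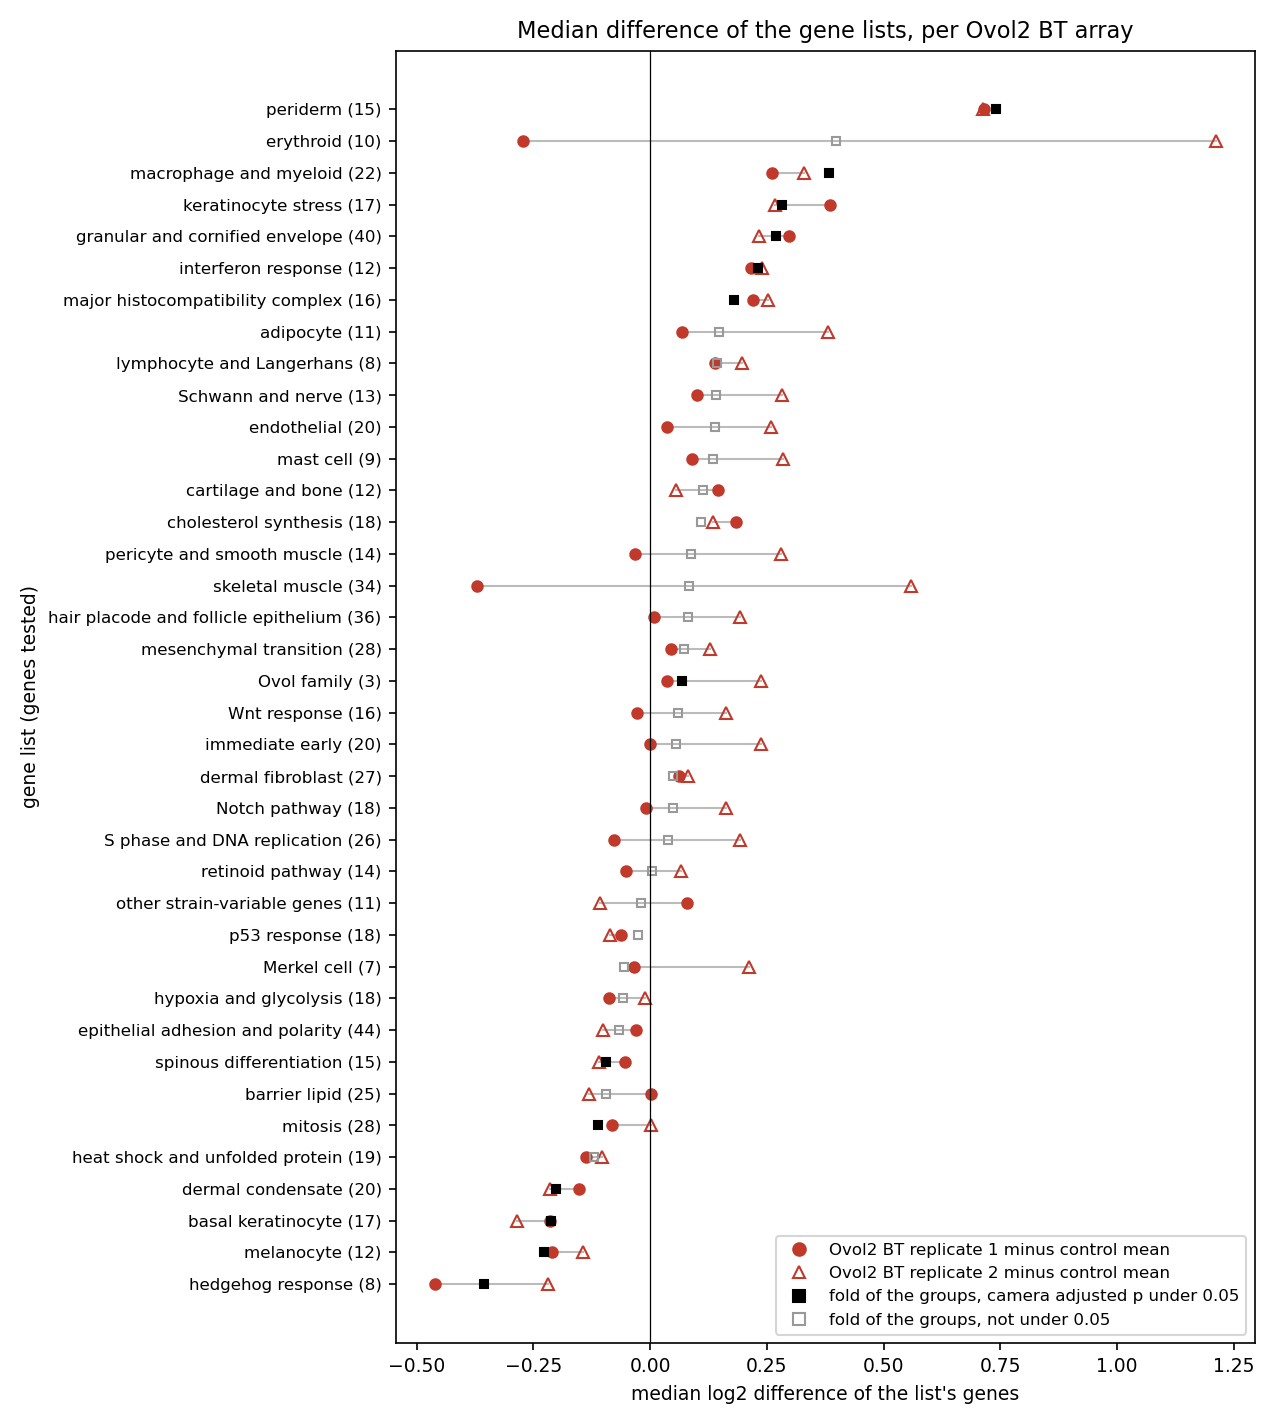
Median log2 difference of each gene list (number of genes tested in brackets; sex genes left out) for each Ovol2 BT array against the control mean, with squares for the fold between groups, black where the camera adjusted p with the preset correlation was under 0.05. Periderm lies at 0.71 on both arrays, whereas erythroid genes lie at -0.27 and 1.21.

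Ovol2 BT replicate 2 stood apart from the other arrays. Over the genes tested, Pearson's r was 0.983 between the control arrays, 0.976 between Ovol2 BT replicate 1 and either control, and 0.930 between the Ovol2 BT arrays; genes are not independent replicates. On Ovol2 BT replicate 2, 893 genes lay over 2-fold lower and 78 over 2-fold higher than the mean of the other 3 arrays, against 33 and 53 on Ovol2 BT replicate 1. Leaving this array out gave 110 changed genes, 68 higher and 42 lower, a fit in which the lone Ovol2 BT array is assumed to vary like the controls. Among those with the smallest p were Prap1, Afp, Guca2b, Fgb and Apoa1, whose values rose mainly on Ovol2 BT replicate 1. Of the 110, 11 were in the cornified envelope list (10 higher, 1 lower), 7 of them Lce1 genes. The periderm and stress lists had 5 each, all higher, hair placode and follicle epithelium 4 (2 higher, 2 lower), basal keratinocytes 3, all lower, and Merkel cells 2. Genes of a list are not independent, so these are counts only, and the cornified envelope and periderm lists had a camera adjusted p = 0.435 with an estimated correlation on all arrays.

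All 4 arrays were labelled female, yet Y-linked genes had signal on both replicate 1 arrays. Eif2s3y read 10.13 and 6.17 on control replicates 1 and 2 and 10.40 and 4.72 on the Ovol2 BT arrays, and Kdm5d read 9.42, 5.76, 9.70 and 4.80 in the same order. Uty, too dim on average to be tested, read 9.19, 5.32, 9.20 and 4.24, and Xist, the transcript of the inactive X chromosome, read 7.07, 13.16, 8.36 and 10.80. The sex list did not pass between genotypes (camera adjusted p = 0.699). The labels also gave control and Ovol2 BT mice different strains, CB6F1 and FVB/N, while the protocol speaks of littermates, so strain and genotype cannot be told apart if the labels are right. Major histocompatibility genes, which differ between strains, had a median of 0.18 over 16 genes (camera adjusted p = 0.0335; adjusted p = 0.435 with an estimated correlation), a call also lost with the length trend removed (0.316), the filter at the 50th percentile (0.219), array weights (0.0502), cyclic loess (0.0565), without control replicate 1 (0.0992) and without Ovol2 BT replicate 1 (0.212). Other strain-variable genes had a median of -0.02 (adjusted p = 0.887). The Ovol family list passed (adjusted p = 0.0176; adjusted p = 0.544 with an estimated correlation) through Ovol2 alone.

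**Figure D3:**
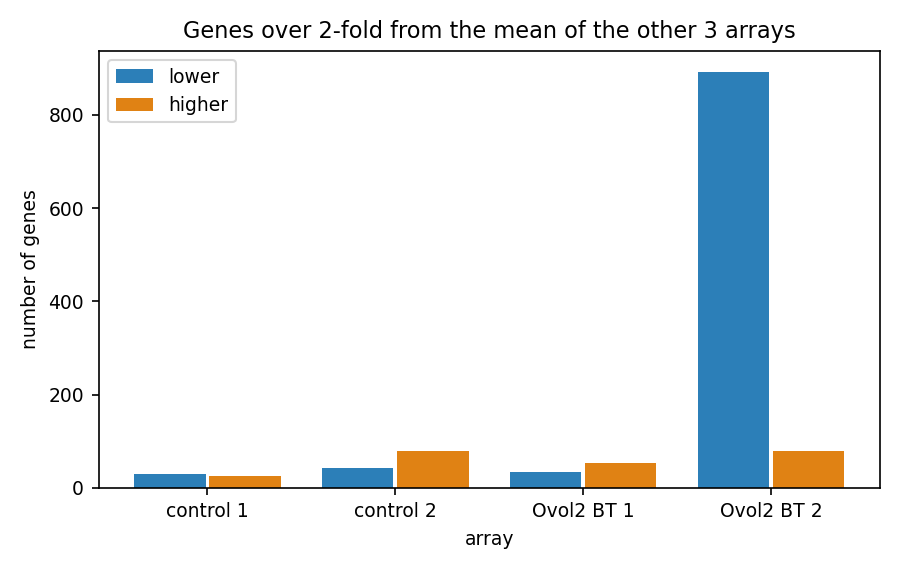
Number of genes on each array over 2-fold lower or higher than the mean of the other 3 arrays. Ovol2 BT replicate 2 has 893 genes lower, the other arrays 30, 43 and 33.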

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

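Array weights, cyclic loess, removal of a trend with gene length and the crossed pairing were tests chosen after seeing the data. The array weights came out equal within each group, 2.11 for both controls and 0.474 for both Ovol2 BT arrays. They thus could not down-weight Ovol2 BT replicate 2 alone. Ovol2 was higher in every alternative fitted to genes, by 4.66 to 5.36, and missed the threshold only with a variance without trend (5.01, adjusted p = 0.059) and cyclic loess (4.99, adjusted p = 0.0543), the highest adjusted p being the former. The 4 genes changed (3 higher, 1 lower) became 10 (7 and 3) with median centring, 8 (6 and 2) at an adjusted p under 0.1, 0 (0 and 0) with a variance without trend, with all probe sets and with cyclic loess, 6 (4 and 2) with array weights and 3 (3 and 0) with the length trend removed; quantile normalisation gave 2 genes lower. With the replicate block there were 9 (7 and 2), and with the pairing crossed 5 (3 and 2); deviations of arrays with the same number correlated at -0.172 across genes, so the numbers were not taken to pair the arrays. Leaving out 1 array gave 4 (without control replicate 2) to 2432 genes changed (without Ovol2 BT replicate 1), 4 to 529 higher and 0 to 1903 lower; the 0 came without control replicate 2, where Akr1d1 fell under the filter. The 11 biology lists shifted became 7 with the filter at the 50th percentile, 0 with an estimated correlation and 0 with fry, and 4 (without Ovol2 BT replicate 1) to 15 without 1 array. Mean folds that reversed were those of erythroid genes without Ovol2 BT replicate 2 (-0.32, range -0.32 to 1.24), hypoxia and glycolysis genes without control replicate 2 (0.17, range -0.29 to 0.17) and skeletal muscle genes without control replicate 2 (-0.29) and without Ovol2 BT replicate 2 (-0.35, range -0.35 to 0.54). The cause was not tested. Other than the 2 set tests, alternatives ended 35 list calls and gave 16 to lists that had not passed, and 26 results had 45 sign changes where neither value passed the threshold. The small number of arrays limits all of these. With 2 per group the fit found 9.6% of simulated 2-fold changes and 83% of those at a log2 fold of 2. That simulation held 200 changed genes and the same noise on all arrays. Across genes, deviations from the other arrays had an SD of 0.511 on Ovol2 BT replicate 2, against 0.260 to 0.292 on the others. The shares found may thus be too high for these data.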

Other observations

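The tests in this part, other than the fit without Ovol2 BT replicate 2, were chosen after the values were seen. Gene families were tested as sets, 9 in all. All 13 Lce1 genes (median log2 fold 0.72, camera adjusted p = 8.96e-24; adjusted p = 0.212 with an estimated correlation) and all 9 Sprr2 genes (0.91, adjusted p = 1.2e-11; adjusted p = 0.165 with an estimated correlation) had higher values, and 23 of 26 keratin-associated protein genes did (0.17, adjusted p = 0.00137; adjusted p = 0.440 with an estimated correlation), though with medians of 0.32 on Ovol2 BT replicate 1 and 0.07 on replicate 2. The Lce1 and Sprr2 lists overlap the cornified envelope list, and copies within a family can share probes. In contrast, 11 of 16 Serpinb genes (-0.23, adjusted p = 0.0109; adjusted p = 0.440 with an estimated correlation) and the 3 Skint genes, of keratinocyte surface proteins (-0.60, adjusted p = 0.00545; adjusted p = 0.307 with an estimated correlation), had lower values. Both rested mainly on Ovol2 BT replicate 2, where the medians were -0.33 for Serpinb and -1.31 for Skint, against 0.00 (0.000542) and -0.15 on replicate 1. Of the others, keratins (27 of 39 higher, median 0.20, adjusted p = 1.93e-05), claudins (15 of 20, 0.17, adjusted p = 0.0278), Lce3 (2 of 3, 0.96, adjusted p = 0.00813) and interleukin 1 genes (7 of 9, 0.15, adjusted p = 0.0113; 0.31 on replicate 1 and 0.09 on replicate 2) leaned higher, with adjusted p of 0.212, 0.373, 0.307 and 0.307 with an estimated correlation. These directions of the medians held under quantile normalisation, median centring and cyclic loess.

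Outside the fixed lists, genes with the smallest p included Lce1k (1.09), the carboxypeptidase Cpa4 (1.56), Gprc5a (1.34) and Pglyrp3 (1.37) on the higher side. On the lower side were the Wnt ligand Wnt16 (-1.55), the receptor phosphatase Ptprz1 (-1.94), the water channel Aqp3 (-1.26), Sox21 (-1.22) and the basal keratinocyte factor Bnc1 (-1.08). None passed over all genes in limma, with adjusted p from 0.119 for Ptprz1 to 0.432 for Bnc1. Of the 110 genes called without Ovol2 BT replicate 2, 100 (90.9%) had the same sign on that array, against 53.4% of all genes. With no effect and shared controls, simulation gave 78.5% (74.5 to 86.4), so part of this share may come from the shared controls. The simulated arrays all had the same noise. Deviations on Ovol2 BT replicate 2 had an SD of 0.511, against 0.260 to 0.292 on the others. The simulated share thus may not hold for these arrays. The 110 also hold Prap1, Afp, Guca2b, Fgb, Apoa1, Ttr, Gzmf, Ctsj and Akr1c18, of which traces of other tissue on replicate 1 are weighed in the last paragraph, so they are not read as an effect of genotype.

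Ovol2 BT replicate 2 had low values for many genes. More blood in the pool would dilute other transcripts alike, but the 5th percentile of the deviations lay 1.18 below their median outside erythroid genes, against 0.339 to 0.386 on the other arrays. Sex of the embryos would split both genotypes the same way, but replicate 2 minus replicate 1 correlated at -0.207 between genotypes. Tissue content also enters this value: the muscle median was -0.77 between controls, but -0.37 and 0.56 on Ovol2 BT replicates 1 and 2. The correlation thus cannot exclude a part of sex. Control replicate 2, also low in Y-linked signal, had 43 genes over 2-fold lower, against 893. This argues against sex as the source of most of these low values. Deviations fell with genomic length on this array (Spearman's rho across genes -0.275, against 0.109 to 0.239 on the others). Each deviation is taken from the mean of the other arrays, so a fall on 1 array brings rises elsewhere. The values of the other arrays are thus no independent reference. The median on this array was -0.0747 in the group of longest genes (3727 genes) and 0.159 in the group of shortest. RNA or labelling quality that lowers long transcripts may contribute, but transcript length was not tested, and these medians are small beside the 5th percentile above. A biological difference between these pools stays open and was not tested.

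Periderm genes were higher and basal keratins lower in Ovol2 BT skin. However, the periderm and basal list calls were lost in camera with an estimated correlation (adjusted p = 0.435 for both). All list calls were lost in that test, which has only 2 degrees of freedom. The periderm and basal calls were also lost in fry (adjusted p = 0.0918 and 0.252). In limma Krt5, Krt15 and Krt14 missed the threshold over all genes (adjusted p = 0.0597, 0.101 and 0.432). Sex of the embryos is argued against, since the periderm median was 0.480 and 0.946 in the 2 pairs of arrays with like Y-linked signal. A lower share of basal cells would lower markers restricted to these cells alike. Krt5, Krt14 and Krt15 were set apart from the other 14 basal markers after their values were seen. The 14 had a median of -0.117 (-0.335 to -0.0118), against -1.41 to -0.66 for the keratins. Bnc1 (-1.08), outside that list, lay in the range of the keratins. How far the 14 are restricted to basal cells was not examined, and Sfn among them is also in the periderm list. The comparison thus cannot decide whether fewer basal cells account for the lower keratins, and this stays open. The strain difference in the labels cannot be told apart from genotype: the 27 strain-variable genes lay at percentile 47.28 of random lists by absolute fold, while the 16 histocompatibility genes among them shifted up as a list (camera adjusted p = 0.0335, lost in the alternatives given with that list). An effect of Ovol2 on these genes is thus a hypothesis, and no control with the transactivator alone was analysed here.

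Afp, read at 7.26 and 7.03 on the control and 10.95 and 9.43 on the Ovol2 BT arrays, was higher on Ovol2 BT replicate 1, as were Fgb, Apoa1, Prap1 and Guca2b, by 2.15, 2.02, 4.74 and 2.95 over the control mean (0.66, 0.57, 1.58 and 0.39 on replicate 2). Liver or gut in the pool would bring its other abundant transcripts. On replicate 1, however, 17 liver markers had a median of 0.160 (0.0255 to 0.365), with Alb at 0.57 but Ttr at 1.55. The 15 gut markers had a median of 0.0560 (-0.0791 to 0.262). Only 9 of the liver and 5 of the gut markers lay above the filter on dim genes, which weakens both medians as evidence. Placenta, decidua or yolk sac was then tried after those had failed and after Gzmf (2.13), Ctsj (1.74) and Akr1c18 (1.34), left out of its list, had been seen among the 110 calls: 5 of 31 markers, Ctsq (4.25), Tpbpa (3.29), Gzmd (2.29), Prl8a2 (2.14) and Tpbpb (2.06), lay over 1 above the control mean on replicate 1, 0 lay that far below it, and 0 lay over 1 above it on replicate 2. That count is another measure than the one used for liver and gut, of which 1 and 0 markers lay over 1. By the median this list (0.360, 0.176 to 0.655) would have failed as they did. Before the list was written, 5 others of the 31 (Apoa4, Apob, Cubn, Amn and Ltf) had been looked at. Only 11 of the 31 lay above the filter on dim genes. Ctsq, Tpbpa, Gzmd, Prl8a2 and Tpbpb all lay under it, and the highest of the 11 on replicate 1 was Cts6 (0.80). Traces of extraembryonic tissue in this pool may contribute to the values on replicate 1 but are not settled, and on replicate 2, where the liver genes Alb (2.06) and Ahsg (1.85) were also above the control mean, the source of Afp and Prap1 stays open.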
